A study of Mus musculus with 9 samples.

How the data were processed

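Lung tissue of 3 groups of mice (Control, Silica, and silica with atractylenolide III, written Silica + ATL-III) was sequenced, with 3 libraries per group. Total RNA was extracted, poly(A) RNA was isolated with oligo(dT) beads and fragmented, and cDNA was primed at random, per the labels' protocols. The protocols name no step that marks the strand, and whether counting used strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. Cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and the mouse build mm10 are named in the submitters' processing notes, without roles. The annotation release is not given in the sources used here.

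The deposited table holds a whole-number count of reads per gene and library, not normalized, for 55359 genes, of which 1438 have no symbol. It also holds the FPKM values that the authors computed, per the file headers. Recomputing FPKM from the counts, the exonic length in the table and the column totals gave every deposited value (100%) within 0.006, so the deposited FPKM carry no scaling between libraries beyond the total count. Chromosomes in the table matched GENCODE M21 (GRCm38, the same assembly as mm10) for 52081 of 52083 shared gene identifiers, but only 1499 start positions (2.88%) did, with a median difference of 133071 bases. The build of those positions is therefore unknown, and only chromosomes are printed.

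Before the data were examined, the design named limma on log2(FPKM + 0.5), because the table was taken to hold FPKM only. Since it holds counts, the main test is edgeR's quasi-likelihood test on the counts with TMM normalization, and the limma fit is given as an alternative. All 9 libraries entered 1 fit of 3 group means (6 residual degrees of freedom), with no covariate. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 15459 genes, 12721 of them protein coding in GENCODE M21. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Standard errors are the log2 fold change divided by the square root of the F statistic. FPKM are printed as deposited, so their ratio can differ from the TMM-scaled fold change.

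Also before the data were examined, 39 gene lists with 980 genes (pathways and cell type markers) were written, of which 38 had at least 5 tested genes. Lists were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, which asks whether a list's genes move 1 way on balance. Camera called 20, 18 and 21 lists (Silica vs Control, Silica + ATL-III vs Silica, Silica + ATL-III vs Control). With an estimated correlation it called 0, 0 and 0 (8, 4 and 9 at an unadjusted p under 0.05, smallest adjusted p = 0.085, 0.28 and 0.064), and fry called 14, 14 and 14. Lists called by both camera at the preset correlation and fry numbered 13, 12 and 13. A list's call by cell type markers describes transcripts in whole lung and names no cell.

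Named genes follow a rule written before the data were examined. Per comparison they are the 8 strongest increases and the 8 strongest decreases among named genes that were called, had no overlap between the libraries of both groups and a mean FPKM of at least 2 in the higher group. To these come the 2 to 3 members with the smallest p from each list that camera called or that had at least 3 called members, with the leading member in the other direction. Always included are Egfr, Mtor, Becn1, Map1lc3b, Sqstm1, Ulk1, Atg5, Atg7, Col1a1, Col1a2, Col3a1, Fn1, Acta2 and Tgfb1. Of the genes so named and called, 69 of 114, 104 of 132 and 96 of 122 kept their call whichever single library was left out. Lost calls of single genes are given below only for the genes always included, so other named genes may also have lost theirs. Small RNA genes with few counts (Mir3097, Mir7240, Snord83b and a U6 copy) and most immunoglobulin segments that met the rule are not described further. Where a group had no count, the fold change is a lower bound against 3 counts over the group, which covers counting error only.

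Depth was even, at 16047175 to 17792481 counts per library. Correlations of log2 values were 0.979 to 0.986 within groups and 0.946 to 0.977 between groups. Counts of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of at least 6.44), so no library was a copy of another. The labels give no batch or date.

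The scripts were tested on simulated counts drawn from the means and library sizes of these samples, with 200 of 15459 genes changed. For Silica vs Control edgeR recovered 22.4%, 76.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 6 false among 135 calls. For Silica + ATL-III vs Silica the shares were 28.4%, 88.1% and 98.5% (8 false of 151), and for Silica + ATL-III vs Control 20.9%, 76.1% and 97.0% (7 false of 136). Camera found the planted list of 30 genes each time, with 1 false among 2 list calls, 1 of 2 and 0 of 1. Changed and planted genes were drawn only from genes above a minimum mean count. Each gene was simulated independently, so false list calls among genes that move together were not tested. In the real lists the estimated correlation reached 0.82 (B cells, Silica + ATL-III vs Control).

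Alternatives were limma on log2(FPKM + 0.5), as the design named it, with pseudocounts 0.1 and 1, quantile normalization or array weights, other filters, upper quartile scaling, FPKM rescaled to TPM, a robust prior, the sample number as a block, only the 6 libraries compared, each library left out, camera with an estimated correlation and fry. Of the limma settings the design named only log2(FPKM + 0.5). Further alternatives were chosen after seeing the data: DESeq2, its size factors in edgeR, library totals alone, and removal of trends with gene length or GC content. For the covariance of the fold changes after silica and with ATL-III, 20 data sets without any effect were simulated, because both comparisons share the Silica libraries. Each gene was drawn independently with its own estimated spread, so variation that many genes of a library share was not simulated.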

Results

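Lung tissue of male C57BL/6J mice was profiled by poly(A) RNA sequencing 28 days after an instillation into the trachea. The study title names autophagy, signalling from the epidermal growth factor receptor (EGFR) to the kinase mTOR, and the lung fibrosis called silicosis. Control mice received saline, Silica mice received 5 mg of silica, the mineral dust that causes silicosis, and Silica + ATL-III mice received silica and also atractylenolide III, a sesquiterpene lactone of Atractylodes plants, at 30 mg/kg per day into the abdomen. The labels mention no injected saline for the other groups and no duration of dosing. Each group held 20 mice, of which the deposited table gives 3 libraries per group, so 9 in all. Total counts ran from 16047175 to 17792481 per library, and 15459 genes passed the expression filter. On the 1st principal component (39.4% of the variance) the Silica + ATL-III libraries stood apart from the other groups, and the 2nd (28.0%) separated Silica from Control. The labels do not say that each library came from a single mouse, so p-values measure the spread between these samples, which may be partly technical. Levels are given as mean FPKM ± SD (n = 3), and changes as log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

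**Figure D1:**
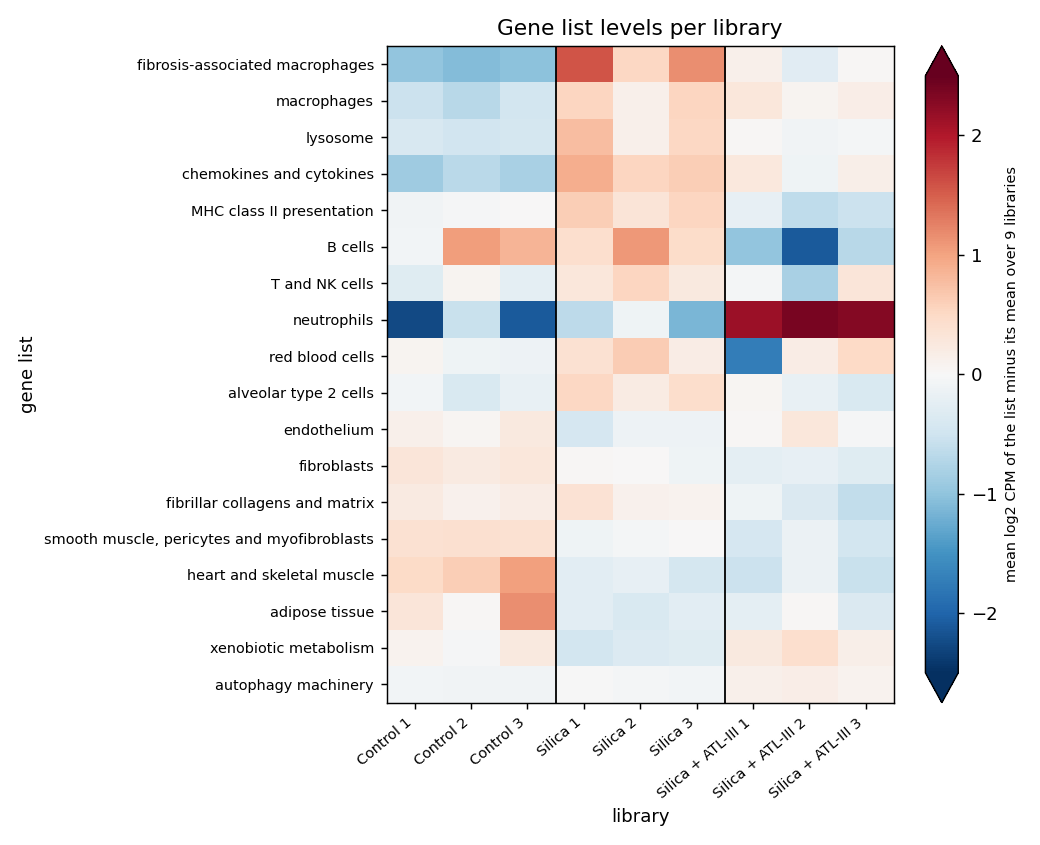
Heat map of 18 gene lists (rows) in the 9 libraries (columns, by group and sample number). Colour gives the mean over a list's genes of the log2 expression relative to the mean of all libraries, and the neutrophil list reads 2.14 to 2.38 in the Silica + ATL-III libraries against -2.26 to -0.10 in the others.

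The comparison of Silica with Control asks how the lung samples differed 28 days after the dust was given. EdgeR called higher 17 of 26 macrophage, 33 of 48 lysosome and 21 of 36 chemokine and cytokine genes, and lower 10 of 20 contractile, 13 of 19 heart and skeletal muscle, 6 of 10 adipose and 7 of 28 endothelial genes. Camera called these lists in the same directions, but none with an estimated correlation (smallest adjusted p = 0.085). Fry called all of them (adjusted p up to 0.039) but the adipose list (0.063). Fry also did not share camera's calls of the neutrophil (fry adjusted p = 0.097), T and NK cell (0.17) and mesothelial lists (0.13). The same held for the oxidative stress (fry adjusted p = 0.070), clock (0.0504) and ribosomal protein lists (0.11). Mmp12, the macrophage elastase, rose from 1.19 ± 0.137 to 175 ± 109 FPKM (log2 fold change 7.32 ± 0.60). Ctsk, the collagen-degrading cathepsin K on chromosome 3, rose from 18.5 ± 1.74 to 328 ± 128 FPKM (4.26 ± 0.29). Retnla, which encodes a secreted protein of alternatively activated macrophages and airway epithelium, rose from 259 ± 12.2 to 2817 ± 1536 FPKM (3.56 ± 0.40).

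Genes with the largest increases after silica included Gpnmb (5.61 ± 0.48), a glycoprotein of lipid-loaded macrophages, and the chemokine Ccl3 (5.54 ± 0.44). The neuropeptide gene Npy had no count in Control and stood at 10.8 ± 9.28 FPKM in Silica, at least 99.5-fold higher against a floor of 3 counts over the group. Awat1, a wax ester synthase, was likewise uncounted in Control and reached 3.20 ± 1.97 FPKM, at least 73.0-fold higher. Cd200r2 went from 0.0333 FPKM, 3 counts in all, to 2.68 ± 0.696 FPKM. Ear6, an eosinophil-type ribonuclease (8.45 ± 0.46), and Ly6i (5.02 ± 0.77) also rose, but both belong to families of near-identical copies, so their counts are uncertain.

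Of 23 fibrosis-associated macrophage genes, 19 rose (20 adjusted over the list alone). Camera called the fibrosis-associated macrophage list higher (adjusted p = 3.1e-34, and adjusted p = 0.13 with an estimated correlation). Their median log2 fold change was 1.71. Of 26 general macrophage markers, 17 rose and 1 fell (19 and 1 adjusted over the list alone). The general macrophage list was called higher by camera (adjusted p = 4.1e-15, and adjusted p = 0.13 with an estimated correlation). Marco, a scavenger receptor, rose by 2.80 ± 0.32 and Cd68 by 2.23 ± 0.25, while Cd163, the haemoglobin scavenger receptor, fell (-1.14 ± 0.19). Of 48 lysosome genes, 33 rose (39 adjusted over the list alone). Camera called the lysosome list higher (adjusted p = 2.7e-27, and adjusted p = 0.18 with an estimated correlation). Its leading members besides Ctsk were the proton pump subunit Atp6v0d2 (2.46 ± 0.20) and the cathepsin Ctsz (1.98 ± 0.22).

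Of 36 chemokine and cytokine genes, 21 rose (22 adjusted over the list alone). The chemokine and cytokine list was called higher by camera (adjusted p = 5.7e-21, and adjusted p = 0.085 with an estimated correlation). Ccl9 rose by 3.48 ± 0.26 and Ccl6 by 2.61 ± 0.22. Of 18 inflammasome and pyroptosis genes, 8 rose (9 adjusted over the list alone), or 5 without Control 3. Camera called the inflammasome and pyroptosis list higher (adjusted p = 1.8e-05, and adjusted p = 0.14 with an estimated correlation). Il1a, the interleukin 1 alpha gene, rose by 2.24 ± 0.21. Of 22 neutrophil markers, 6 rose (7 adjusted over the list alone), or 3 without Control 1. The neutrophil list was called higher by camera (adjusted p = 9.7e-05, and adjusted p = 0.39 with an estimated correlation). The list's median of 0.50 became -0.079 without Silica 2, 0.093 without Control 1, 0.087 without Control 3 and 1.58 without Control 2, whose neutrophil score of -0.56 stood above -2.26 and -2.10 in its group. Its called members included the chemokine receptor Cxcr1 (3.99 ± 0.36) and the iron-sequestering lipocalin Lcn2 (2.93 ± 0.28). Of 13 MHC class II presentation genes, 5 rose (7 adjusted over the list alone), or 2 to 3 without Control 1, Control 2, Control 3, Silica 1 or Silica 3. Camera called the MHC class II presentation list higher (adjusted p = 0.00083, and adjusted p = 0.23 with an estimated correlation). Ctss, which trims the invariant chain, rose by 2.20 ± 0.28 and the invariant chain gene Cd74 by 1.09 ± 0.23.

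Alveolar type 2 cells make surfactant. Of 21 alveolar type 2 genes, 12 rose (16 adjusted over the list alone), or 5 to 6 without Control 2, Control 3 or Silica 1. The alveolar type 2 list was called higher by camera (adjusted p = 1.2e-08, and adjusted p = 0.33 with an estimated correlation). Sftpd, surfactant protein D, went from 451 ± 56.7 to 875 ± 68.4 FPKM (1.06 ± 0.19), and the chitinase-like Chil1 rose by 1.70 ± 0.24. Of 28 oxidative stress genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone), or 6 to 7 without Control 1, Control 2, Control 3 or Silica 1. Camera called the oxidative stress list higher (adjusted p = 0.00048, and adjusted p = 0.42 with an estimated correlation). Their median of 0.18 turned negative when FPKM was rescaled to TPM, and the camera call was lost with limma and quantile normalization (adjusted p = 0.10). Hmox1, heme oxygenase, rose by 1.38 ± 0.20 and the cystine importer Slc7a11 by 3.43 ± 0.50. Of 23 cell cycle genes, 6 rose (10 adjusted over the list alone), or 1 to 2 without Control 1, Control 2, Silica 1 or Silica 3. The cell cycle list was called higher by camera (adjusted p = 0.00044, and adjusted p = 0.39 with an estimated correlation).

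Genes of contractile cells went the other way. Of 20 smooth muscle, pericyte and myofibroblast genes, 10 fell (10 adjusted over the list alone), or 6 without Control 2 or Silica 1. Camera called the smooth muscle, pericyte and myofibroblast list lower (adjusted p = 1.4e-05, and adjusted p = 0.18 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, fell from 37.6 ± 2.45 to 19.0 ± 3.38 FPKM (-0.89 ± 0.15). Of 19 heart and skeletal muscle genes, 13 fell (15 adjusted over the list alone), or 5 to 8 without Control 3, Silica 1 or Silica 3. The heart and skeletal muscle list was called lower by camera (adjusted p = 2.8e-09, and adjusted p = 0.14 with an estimated correlation). Tnnt2, cardiac troponin T, fell (-1.13 ± 0.19). Of 10 adipose genes, 6 fell (7 adjusted over the list alone), or 1 to 2 without Control 3, Silica 1 or Silica 3. Camera called the adipose list lower (adjusted p = 0.0014, and adjusted p = 0.38 with an estimated correlation). Control 3 had the highest scores of its group for adipose (1.15 against 0.31 and 0.02) and for heart and skeletal muscle genes (1.03 against 0.49 and 0.62). Whether the samples differed in their share of heart, muscle and fat tissue was not tested, so these decreases cannot be credited to the lung itself. Cidec, a lipid droplet gene, fell (-1.41 ± 0.25). Of 28 endothelial genes, 7 fell (12 adjusted over the list alone), or 1 to 4 without Control 1, Control 3, Silica 1 or Silica 3. The endothelial list was called lower by camera (adjusted p = 2.0e-05, and adjusted p = 0.38 with an estimated correlation). The endothelial receptor Tie1 fell (-0.80 ± 0.15). Of 24 xenobiotic metabolism genes, 9 fell (12 adjusted over the list alone), or 2 to 5 without Control 1, Control 3 or Silica 1. Camera called the xenobiotic metabolism list lower (adjusted p = 1.8e-05, and adjusted p = 0.23 with an estimated correlation). The monooxygenase Fmo2 was lower as well (-0.84 ± 0.16). The dendritic cell lectin Cd209a was among the strongest decreases (-2.12 ± 0.32).

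Of 22 fibroblast genes, 7 fell (9 adjusted over the list alone), or 0 to 3 without Control 1, Control 2, Control 3, Silica 1 or Silica 3. The fibroblast list was called lower by camera (adjusted p = 0.0019, and adjusted p = 0.18 with an estimated correlation). Fibrillar collagen and other matrix genes, tested together as 1 list, were not called after silica. Of this list 3 of 34 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.65, adjusted p = 0.91 with an estimated correlation). Fibrillar collagens were not tested as a list of their own. The number that rose was 0 to 5 without Control 1, Control 2, Control 3, Silica 1 or Silica 2, and the number that fell was 0 to 1 without Control 1, Control 3, Silica 1 or Silica 3. Limma with array weights called 4 higher and 16 lower, edgeR on FPKM rescaled to TPM 3 and 6, and edgeR on only the 6 libraries compared 5 and 6. Col1a1 stood at 6.46 ± 1.32 FPKM in Control and 5.18 ± 0.476 in Silica, Col1a2 at 15.8 ± 0.823 and 24.5 ± 6.76, and Col3a1 at 34.8 ± 3.04 and 59.9 ± 18.9, each short of the edgeR threshold (adjusted p = 0.45, 0.060 and 0.092). Fibronectin, Fn1, rose by 0.87 ± 0.22, Tgfb1 by 0.64 ± 0.15, and the smooth muscle actin gene Acta2 fell (-0.39 ± 0.12). None of these last 3 calls was held by every reduced data set: Fn1 (adjusted p up to 0.080 without Control 1, Control 2, Control 3 or Silica 1), Tgfb1 (adjusted p up to 0.081 without Control 2, Control 3 or Silica 1) and Acta2 (adjusted p up to 0.16 without Control 1, Control 2, Control 3, Silica 1, Silica 2 or Silica 3) by edgeR. Of 30 TGF-beta pathway genes, 7 rose and 4 fell (8 and 6 adjusted over the list alone), or 3 to 4 without Control 2, Control 3 or Silica 1, and camera made no call (adjusted p = 0.45, and adjusted p = 0.70 with an estimated correlation). Inhba, an activin subunit, rose by 3.63 ± 0.38, Ltbp2 by 1.21 ± 0.22, and Ltbp4 fell (-0.98 ± 0.17).

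After silica edgeR called 16.9% of all tested genes. Egfr stood at 2.73 ± 0.201 FPKM in Control and 1.92 ± 0.235 in Silica (edgeR adjusted p = 0.16), Mtor at 2.60 ± 0.0379 and 2.26 ± 0.330 (0.60), and the autophagy gene Becn1 at 14.9 ± 0.459 and 13.4 ± 1.42 (0.75). For Map1lc3b, which encodes the LC3B protein of autophagosome membranes, the levels were 18.0 ± 0.621 and 19.0 ± 2.41 FPKM (0.33). The cargo receptor Sqstm1 stood at 55.0 ± 3.22 and 72.7 ± 17.7 FPKM (0.074), and Atg7 at 3.00 ± 0.311 and 3.67 ± 0.382 (0.064). Atg5 rose by 0.55 ± 0.12 and the initiating kinase Ulk1 fell (-0.40 ± 0.13), but neither call held throughout: Atg5 (adjusted p up to 0.069 without Control 3 or Silica 1), Ulk1 (adjusted p up to 0.18 without Control 1, Control 2, Control 3, Silica 1 or Silica 3) by edgeR. Over the autophagy machinery, 3 of 45 genes rose and 1 fell (2 rose adjusted over the list alone). The rising genes numbered 0 to 7 without Control 3, Silica 1 or Silica 2. Camera made no call on that list (adjusted p = 0.52). In the EGF receptor family 3 of 18 rose (3 adjusted over the list alone), or 1 without Control 1, Control 2 or Control 3. In the PI3K-AKT-mTOR list 8 of 50 rose and 4 fell (9 and 6 adjusted over the list alone), and the rising genes numbered 3 to 5 without Control 1, Control 2, Control 3, Silica 1 or Silica 3. Camera called neither of these lists. These values, here and in the comparisons below, are of transcripts, and the activity of EGFR, mTOR or autophagy was not measured in them.

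In total edgeR called 2615 genes after silica, 1408 higher and 1207 lower, of which 365 and 148 changed at least 2-fold. With 1 library left out the total was 1179 (Control 1), 1147 (Control 2), 862 (Control 3), 865 (Silica 1), 3944 (Silica 2) and 1202 (Silica 3). Of the calls, 53.8% were higher, against 17.4% when FPKM was rescaled to TPM, 33.0% with library totals alone and 33.6% with limma on the deposited FPKM, which shifted the median gene by -0.19, -0.10 and -0.10.

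**Figure D2:**
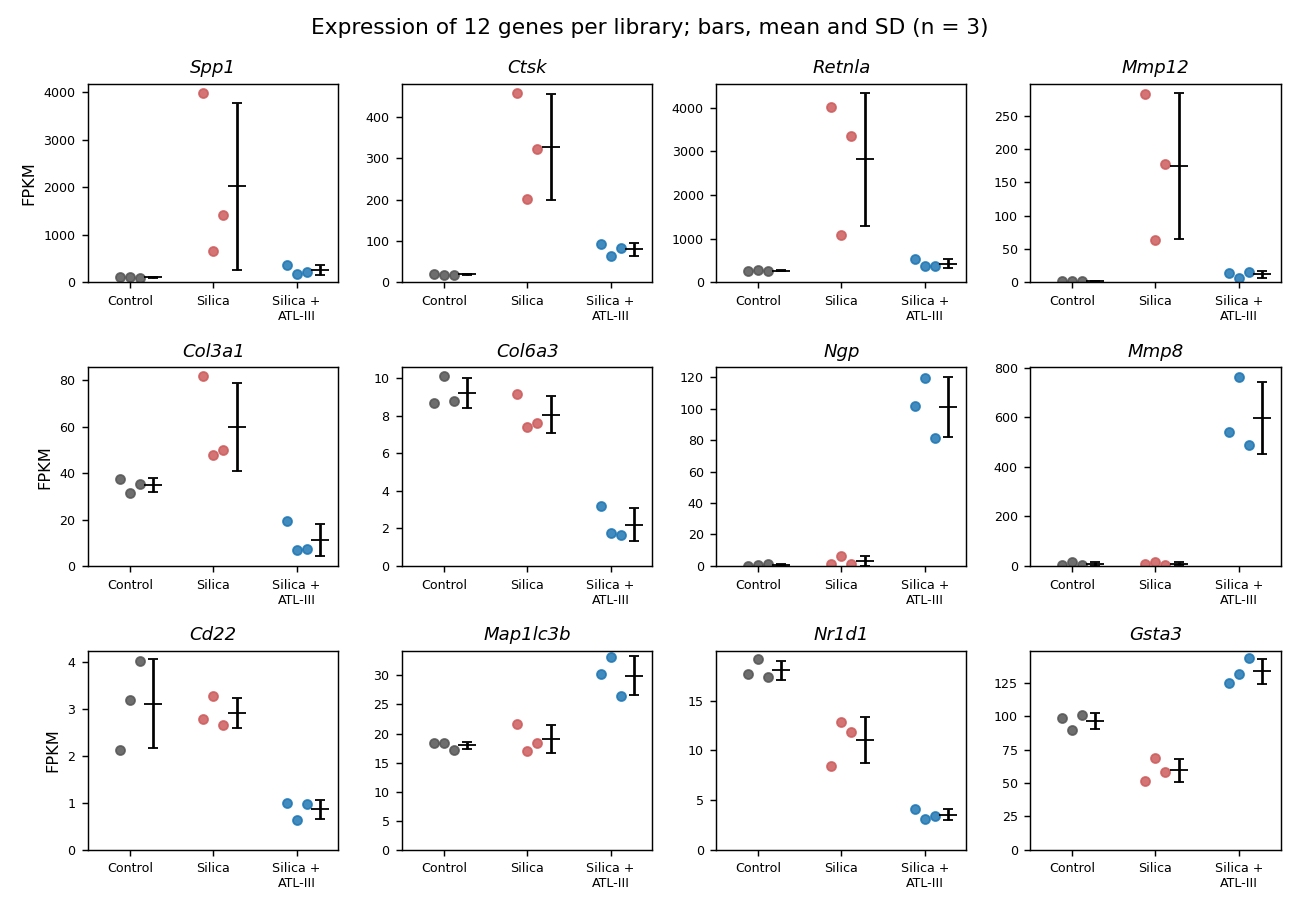
FPKM of 12 genes in the 9 libraries, each dot 1 library, with bars for the mean and SD of the 3 libraries per group. Spp1, Ctsk, Retnla and Mmp12 are highest in Silica, Ngp and Mmp8 in Silica + ATL-III, and Cd22 is lowest in Silica + ATL-III.

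Silica + ATL-III against Silica shows how the lung samples differed when ATL-III was given with silica. No group received ATL-III without silica, and no injected control is named. A changed silica response therefore cannot be told apart from an effect that ATL-III or injection would have in any lung. EdgeR called 18 of 22 neutrophil genes higher than in Silica, and lower 17 of 17 B cell, 10 of 13 MHC class II, 15 of 34 collagen and matrix, 18 of 23 fibrosis-associated macrophage and 25 of 48 lysosome genes. These lists were called by camera as well, but none with an estimated correlation (smallest adjusted p = 0.28). Fry called all of them (adjusted p up to 0.033) but the lysosome list (0.062). Fry also did not share camera's calls of the T and NK cell (fry adjusted p = 0.16), plasma cell (0.16) and endothelial lists (0.096). The same held for the mesothelial (fry adjusted p = 0.13) and immediate-early lists (0.11). Mmp8, neutrophil collagenase, rose from 9.27 ± 5.38 to 597 ± 145 FPKM (6.04 ± 0.60). Col3a1 fell from 59.9 ± 18.9 to 11.2 ± 6.98 FPKM (-2.41 ± 0.36), and Spp1, the matricellular protein osteopontin, from 2013 ± 1748 to 249 ± 102 (-3.02 ± 0.55).

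Of 22 neutrophil markers, 18 rose (20 adjusted over the list alone). Camera called the neutrophil list higher (adjusted p = 4.5e-17, and adjusted p = 0.28 with an estimated correlation). Their median log2 fold change was 2.96. Ngp, a protein of neutrophil granules, rose by 5.09 ± 0.50 and Hdc, which makes histamine, by 1.54 ± 0.18. Other genes among the strongest increases were the decoy receptor Il1r2 (6.20 ± 0.72) and the secreted factor Prok2 (6.38 ± 0.47), which went from 0.123 ± 0.143 to 10.2 ± 0.263 FPKM. The stefins Stfa2 (5.77 ± 0.53) and Stfa3 (5.76 ± 0.43) and Ifitm6 (5.23 ± 0.45) rose as well, with counts that near-identical copies can share. Monocyte genes Ly6c2 (1.82 ± 0.26) and F13a1 (2.37 ± 0.21) were higher, and Xcr1, of cross-presenting dendritic cells, was lower (-1.40 ± 0.28). Of 22 monocyte and dendritic cell markers, 9 rose and 5 fell (9 and 6 adjusted over the list alone), or 5 without Silica 1, and camera made no call (adjusted p = 0.11, and adjusted p = 0.41 with an estimated correlation). Camera called that list higher without Silica 3 (adjusted p = 0.046) or Silica + ATL-III 2 (adjusted p = 0.031). Of 18 inflammasome and pyroptosis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), or 3 without Silica 3 or Silica + ATL-III 1, and camera made no call (adjusted p = 0.46, and adjusted p = 0.80 with an estimated correlation). Mefv, of that list, rose (2.64 ± 0.36).

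Of 17 B cell markers, 17 fell (17 adjusted over the list alone). The B cell list was called lower by camera (adjusted p = 8.8e-13, and adjusted p = 0.41 with an estimated correlation). The median was -1.88. Cd22, an inhibitory B cell receptor, fell from 2.90 ± 0.323 to 0.863 ± 0.202 FPKM (-1.73 ± 0.24), and the B cell transcription factor Ebf1 fell too (-1.06 ± 0.18). Of 21 T and NK cell markers, 4 fell and 1 rose (4 and 1 adjusted over the list alone), or 2 to 10 without Silica 1, Silica 3, Silica + ATL-III 2 or Silica + ATL-III 3. Camera called the T and NK cell list lower (adjusted p = 0.012, and adjusted p = 0.68 with an estimated correlation). That camera call was lost without Silica 2 or Silica + ATL-III 2 (adjusted p up to 0.13). The T cell adhesion gene Cd2 fell (-0.97 ± 0.18). Of 13 MHC class II presentation genes, 10 fell (11 adjusted over the list alone). The MHC class II presentation list was called lower by camera (adjusted p = 7.0e-08, and adjusted p = 0.28 with an estimated correlation). Ciita, the master regulator of these genes, fell (-1.35 ± 0.18), as did H2-DMb1 (-0.95 ± 0.15). The immunoglobulin heavy chain gene Igha was lower by edgeR (-1.80 ± 0.31).

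Of 34 collagen and matrix genes, 15 fell and 3 rose (20 and 3 adjusted over the list alone). Camera called the collagen and matrix list lower (adjusted p = 3.8e-06, and adjusted p = 0.41 with an estimated correlation). The median was -0.47. Col6a3 fell from 8.05 ± 0.973 to 2.20 ± 0.871 FPKM (-1.86 ± 0.22), Col1a2 by a log2 change of -1.80 ± 0.26 and the proteoglycan Lum by -1.36 ± 0.17, while the proteoglycan Vcan rose (2.10 ± 0.23). Col1a1 (-0.82 ± 0.20) and Fn1 (-0.80 ± 0.22) also fell, but not in every reduced data set: Col1a1 (adjusted p up to 0.060 without Silica + ATL-III 2), Fn1 (adjusted p up to 0.092 without Silica 1, Silica + ATL-III 2 or Silica + ATL-III 3) by edgeR. Acta2 stood at 16.0 ± 1.27 and 14.4 ± 2.30 FPKM and Tgfb1 at 3.85 ± 0.291 and 3.41 ± 0.478, neither past the edgeR threshold (adjusted p = 0.47 and 0.49). Of 30 TGF-beta pathway genes, 10 fell and 4 rose (11 and 6 adjusted over the list alone), and camera made no call (adjusted p = 0.076, and adjusted p = 0.41 with an estimated correlation). The list was called lower without Silica + ATL-III 2 (adjusted p = 0.046). Inhba (-2.67 ± 0.36), Ltbp2 (-1.85 ± 0.22) and Tgfb2 (-1.24 ± 0.15) fell and Tgfbr3 rose (0.96 ± 0.15). Of 22 fibroblast genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone). The fibroblast list was called lower by camera (adjusted p = 0.026, and adjusted p = 0.41 with an estimated correlation). This call was lost without Silica 2 or Silica + ATL-III 3 (adjusted p up to 0.086) and with limma and quantile normalization. Mfap5 fell (-1.31 ± 0.12) and Pi16, of adventitial fibroblasts, rose (2.31 ± 0.30).

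Of 23 fibrosis-associated macrophage genes, 18 fell and 1 rose (21 and 1 adjusted over the list alone). Camera called the fibrosis-associated macrophage list lower (adjusted p = 2.7e-11, and adjusted p = 0.41 with an estimated correlation). Of 48 lysosome genes, 25 fell and 1 rose (28 and 2 adjusted over the list alone), or 16 without Silica 1 and 14 without Silica + ATL-III 2. The lysosome list was called lower by camera (adjusted p = 3.0e-08, and adjusted p = 0.51 with an estimated correlation). Mmp12 fell from 175 ± 109 to 12.1 ± 5.21 FPKM (-3.85 ± 0.50), Ctsk by a log2 change of -2.04 ± 0.26 and Retnla by -2.72 ± 0.38, and the lipoprotein-associated phospholipase Pla2g7 rose (1.32 ± 0.27). Of 36 chemokine and cytokine genes, 18 fell and 2 rose (22 and 4 adjusted over the list alone), or 9 without Silica 1 and 10 without Silica + ATL-III 2. Camera called the chemokine and cytokine list lower (adjusted p = 5.2e-05, and adjusted p = 0.41 with an estimated correlation). Ccl3 (-2.22 ± 0.33) and Cxcl12 (-1.50 ± 0.24) fell. Of 21 alveolar type 2 genes, 12 fell (12 adjusted over the list alone), or 7 without Silica 3. The alveolar type 2 list was called lower by camera (adjusted p = 5.1e-07, and adjusted p = 0.41 with an estimated correlation). Genes that fell included the lipid enzymes Lpcat1 (-1.13 ± 0.12) and Scd1 (-1.64 ± 0.23). Of 26 general macrophage markers, 7 fell and 3 rose (10 and 3 adjusted over the list alone), or 3 without Silica 1, Silica 3 or Silica + ATL-III 2, and camera made no call (adjusted p = 0.11, and adjusted p = 0.68 with an estimated correlation). Without Silica 2 camera called that list lower (adjusted p = 0.0020). Npy (-3.76 ± 0.80), the anion transporter Slc26a4 (-2.91 ± 0.43) and the non-classical MHC gene H2-M2 (-3.58 ± 0.53) were among the strongest decreases.

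Several drug-metabolising genes rose with ATL-III from their level in Silica. Of 24 xenobiotic metabolism genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone). Camera called the xenobiotic metabolism list higher (adjusted p = 9.2e-09, and adjusted p = 0.28 with an estimated correlation). Gsta3, a glutathione transferase, rose from 59.4 ± 8.64 to 134 ± 9.62 FPKM (1.19 ± 0.12). Silica had lowered 9 of the 24 xenobiotic genes, so part of the rise was a return toward Control. Against Control 6 of 24 were higher and 1 lower (median 0.27), and camera made no call (adjusted p = 0.065). That median turned negative when FPKM was rescaled to TPM and with limma and quantile normalization. Of 28 oxidative stress genes, 7 rose and 6 fell (8 and 7 adjusted over the list alone), or 4 without Silica 2 or Silica + ATL-III 2, and camera made no call (adjusted p = 0.68, and adjusted p = 0.95 with an estimated correlation). In that list the metallothionein Mt2 rose by 3.02 ± 0.56, and the peroxidase Prdx1 fell (-1.37 ± 0.25). Of 28 endothelial genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone). The endothelial list was called higher by camera (adjusted p = 0.0083, and adjusted p = 0.63 with an estimated correlation). This call was lost without Silica 1 (adjusted p = 0.11). Lyve1, a hyaluronan receptor of lymphatic vessels, rose by 1.47 ± 0.20.

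Of 45 autophagy machinery genes, 11 rose and 4 fell (12 and 5 adjusted over the list alone), or 6 without Silica 3 and 7 without Silica + ATL-III 2. Camera called the autophagy machinery list higher (adjusted p = 0.028, and adjusted p = 0.41 with an estimated correlation). The camera call was lost without Silica 2 (adjusted p = 0.069) and when FPKM was rescaled to TPM. Map1lc3b rose from 19.0 ± 2.41 to 29.9 ± 3.36 FPKM (0.67 ± 0.13), Ulk1 from 5.28 ± 0.741 to 9.25 ± 1.46 (0.83 ± 0.13), and Atg9a, a membrane protein of autophagosome formation, by 1.01 ± 0.18. Atg5 fell (-0.47 ± 0.12), a call that single libraries decided: Atg5 (adjusted p up to 0.074 without Silica 1, Silica 3, Silica + ATL-III 1 or Silica + ATL-III 2) by edgeR. Egfr stood at 1.92 ± 0.235 FPKM in Silica and 2.73 ± 0.800 with ATL-III (edgeR adjusted p = 0.074), Mtor at 2.26 ± 0.330 and 2.55 ± 0.365 (0.31), Becn1 at 13.4 ± 1.42 and 15.6 ± 0.751 (0.099). Sqstm1 stood at 72.7 ± 17.7 and 76.5 ± 13.2 FPKM (0.79) and Atg7 at 3.67 ± 0.382 and 3.56 ± 0.376 (0.90). In the EGF receptor list 2 of 18 genes rose and 3 fell (4 and 4 adjusted over the list alone), and the falling genes numbered 1 without Silica 1, Silica 3 or Silica + ATL-III 1. Adam10, a shedding protease, fell (-0.47 ± 0.11). In the PI3K-AKT-mTOR list 10 of 50 rose and 4 fell (13 and 6 adjusted over the list alone), and the rising genes numbered 4 to 6 without Silica 3, Silica + ATL-III 1 or Silica + ATL-III 2. The translation repressor Eif4ebp1 rose (0.89 ± 0.16), and camera called neither list.

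EdgeR called 3279 genes between these groups, 1726 higher and 1553 lower, of which 595 and 350 changed at least 2-fold. The total was 2103 without Silica 1, 2044 without Silica 3 and 1925 without Silica + ATL-III 2. Of the calls, 52.6% were higher, against 42.5% with upper quartile scaling and 29.8% when FPKM was rescaled to TPM, which shifted the median gene by -0.12.

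Silica + ATL-III against Control shows how far the treated lungs stood from those given saline alone. EdgeR called 21 of 22 neutrophil, 12 of 26 macrophage and 9 of 18 inflammasome genes higher, and 15 of 17 B cell, 19 of 34 collagen and matrix, 11 of 22 fibroblast and 13 of 20 contractile genes lower. Camera's calls of these lists were all lost with an estimated correlation (smallest adjusted p = 0.064). Fry called every 1 of them (adjusted p up to 0.024). Fry did not share camera's calls of the lysosome (fry adjusted p = 0.073), fibrosis-associated macrophage (0.0501), interferon-induced (0.23) and MHC class II lists (0.052). The same held for the complement (fry adjusted p = 0.069), adipose (0.12), immediate-early (0.067) and ribosomal protein lists (0.22). Saa3, an acute phase protein, rose from 2.88 ± 3.17 to 272 ± 83.7 FPKM (6.68 ± 0.67). Col3a1 was lower than in Control, at 11.2 ± 6.98 against 34.8 ± 3.04 FPKM (-1.52 ± 0.35), as was Col1a1, at 2.89 ± 0.882 against 6.46 ± 1.32 (-1.04 ± 0.20).

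Of 22 neutrophil markers, 21 rose (22 adjusted over the list alone). The neutrophil list was called higher by camera (adjusted p = 5.2e-33, and adjusted p = 0.064 with an estimated correlation). The median was 3.42, with Ngp at 7.48 ± 0.61, Mmp8 at 6.22 ± 0.60 and Lcn2 at 3.75 ± 0.29. Prok2 had no count in Control and stood at 10.2 ± 0.263 FPKM, at least 318.3-fold higher against a floor of 3 counts over the group. Ear6 (7.43 ± 0.48) and Cstdc5 (6.26 ± 0.71), from families of near-identical copies, were also higher. Of 26 general macrophage markers, 12 rose (15 adjusted over the list alone), or 7 without Control 2. Camera called the general macrophage list higher (adjusted p = 6.3e-08, and adjusted p = 0.15 with an estimated correlation). The Fc receptor Fcgr3 rose by 2.52 ± 0.16. Of 23 fibrosis-associated macrophage genes, 10 rose and 1 fell (15 and 2 adjusted over the list alone). The fibrosis-associated macrophage list was called higher by camera (adjusted p = 4.3e-07, and adjusted p = 0.43 with an estimated correlation). Gpnmb still stood 3.40 ± 0.44 above Control on the log2 scale. Of 48 lysosome genes, 15 rose (17 adjusted over the list alone), or 8 to 9 without Control 1, Control 2, Control 3 or Silica + ATL-III 1. Camera called the lysosome list higher (adjusted p = 1.8e-05, and adjusted p = 0.52 with an estimated correlation). Ctsk was higher by 2.22 ± 0.27. Of 36 chemokine and cytokine genes, 14 rose and 3 fell (17 and 3 adjusted over the list alone). The chemokine and cytokine list was called higher by camera (adjusted p = 5.0e-06, and adjusted p = 0.15 with an estimated correlation). Of 18 inflammasome and pyroptosis genes, 9 rose (12 adjusted over the list alone), or 4 without Control 1 and 5 without Control 3. Camera called the inflammasome and pyroptosis list higher (adjusted p = 9.6e-07, and adjusted p = 0.088 with an estimated correlation). Cxcl2, a neutrophil attractant, rose by 4.59 ± 0.61 and the inflammatory caspase Casp4 by 1.68 ± 0.16.

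Of 17 B cell markers, 15 fell (16 adjusted over the list alone). The B cell list was called lower by camera (adjusted p = 6.6e-13, and adjusted p = 0.27 with an estimated correlation). The median was -1.97, and H2-Ob fell (-1.74 ± 0.28). Of 34 collagen and matrix genes, 19 fell and 2 rose (20 and 2 adjusted over the list alone), or 12 without Control 3. Camera called the collagen and matrix list lower (adjusted p = 1.3e-07, and adjusted p = 0.35 with an estimated correlation). Col6a3 (-1.95 ± 0.22) and Lum (-1.72 ± 0.17) fell, and Col1a2 (-1.05 ± 0.25) lost its call once: Col1a2 (adjusted p up to 0.057 without Silica + ATL-III 2) by edgeR. Of 22 fibroblast genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone). The fibroblast list was called lower by camera (adjusted p = 1.2e-07, and adjusted p = 0.064 with an estimated correlation). Mfap5 fell (-1.12 ± 0.12). Of 20 smooth muscle, pericyte and myofibroblast genes, 13 fell (15 adjusted over the list alone). Camera called the smooth muscle, pericyte and myofibroblast list lower (adjusted p = 2.7e-12, and adjusted p = 0.064 with an estimated correlation). The myosin kinase Mylk fell (-1.02 ± 0.12), as did Acta2 (-0.53 ± 0.12) with an unstable call: Acta2 (adjusted p up to 0.062 without Control 1 or Silica + ATL-III 1) by edgeR. Of 19 heart and skeletal muscle genes, 15 fell (17 fell and 1 rose adjusted over the list alone). The heart and skeletal muscle list was called lower by camera (adjusted p = 5.1e-10, and adjusted p = 0.088 with an estimated correlation). Myoglobin, Mb, fell (-1.76 ± 0.25). The receptor Fgfr4 (-3.24 ± 0.33) and the amino acid transporter Slc7a10 (-2.97 ± 0.23) were among the strongest decreases, next to segments of the immunoglobulin kappa locus such as Igkj3 (30.4 FPKM in Control and 1.60 with ATL-III, 3 counts in all), which near-identical segments make uncertain. Fn1 stood at 16.5 ± 1.51 and 16.0 ± 1.66 FPKM (edgeR adjusted p = 0.86) and Tgfb1 at 2.65 ± 0.394 and 3.41 ± 0.478 (0.053).

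Of 45 autophagy machinery genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone), or 4 to 7 without Control 1, Control 2, Control 3, Silica + ATL-III 1 or Silica + ATL-III 2. Camera called the autophagy machinery list higher (adjusted p = 0.0025, and adjusted p = 0.14 with an estimated correlation). The median turned negative and the call was lost when FPKM was rescaled to TPM. Map1lc3b rose from 18.0 ± 0.621 to 29.9 ± 3.36 FPKM (0.86 ± 0.13) and Gabarapl1, of the same protein family, by 0.90 ± 0.14. Calls of Sqstm1 (0.59 ± 0.18) and Ulk1 (0.43 ± 0.13) were less stable: Sqstm1 (adjusted p up to 0.15 without Control 1, Control 2, Control 3, Silica + ATL-III 1 or Silica + ATL-III 2), Ulk1 (adjusted p up to 0.12 without Control 1, Control 2, Control 3, Silica + ATL-III 1 or Silica + ATL-III 2) by edgeR. Egfr stood at 2.73 ± 0.201 and 2.73 ± 0.800 FPKM (edgeR adjusted p = 0.72), Mtor at 2.60 ± 0.0379 and 2.55 ± 0.365 (0.68), and Becn1 at 14.9 ± 0.459 and 15.6 ± 0.751 (0.21). Atg5 stood at 20.4 ± 1.30 and 19.8 ± 2.15 FPKM (0.70) and Atg7 at 3.00 ± 0.311 and 3.56 ± 0.376 (0.092). Of 35 interferon-induced genes, 9 rose (10 adjusted over the list alone). The interferon-induced list was called higher by camera (adjusted p = 0.00024, and adjusted p = 0.67 with an estimated correlation). This call was lost without Silica + ATL-III 1 (adjusted p = 0.54), whose mean score was 1.14 against -0.34 and 0.07 in its group.

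EdgeR called 2451 genes here, 1413 higher and 1038 lower, of which 627 and 263 changed at least 2-fold, and 1590 without Control 1 or 1474 without Control 3. Of the calls, 57.6% were higher, against 47.4% with upper quartile scaling, 46.7% with quantile normalization, 34.6% with library totals alone, 35.2% with limma on the deposited FPKM and 12.7% when FPKM was rescaled to TPM. The last 3 shifted the median gene by -0.12, -0.12 and -0.30.

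Setting both steps side by side asks which silica genes moved back with ATL-III. Of the 2615 genes changed by silica, 1000 (38.2%) changed in the opposite direction with ATL-III, 583 up then down and 417 down then up, and 101 changed further in the same direction. Ctsk (log2 fold change 4.26, then -2.04), Mmp12 (7.32, then -3.85) and Fmo2 (-0.84 after silica, from 125 back to 272 FPKM) were of the first kind, and Lcn2 and Casp4 went from 289.8 to 504 and from 14.8 to 24.4 FPKM. Of the 1000 genes, 890 were not called against Control, 67 were still called on the silica side and 43 on the other side. Independent lists of these sizes would share 276 genes in opposite and 278 in the same direction. Both comparisons share the Silica libraries, which by itself makes their fold changes correlate negatively. The 3 Silica libraries cannot be split so that both parts keep 2, so part of the excess may come from the shared Silica libraries. The covariance of the fold changes across genes was -0.17, against -0.05 in 20 simulations without any effect (from -0.05 to -0.04), a difference of -0.13. The simulations drew each gene independently, so their narrow range leaves out variation that many genes of a library share. With 1 real library left out the covariance ran from -0.30 to -0.14. The correlation across genes was -0.42, weaker than the -0.49 of the simulations, and genes are not independent replicates. The count of 1000 became 507, 499 and 425 without Control 1, 2 and 3, 310, 1906 and 421 without Silica 1, 2 and 3, and 562 without Silica + ATL-III 2, and the covariance became -0.30 without Silica 2.

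**Figure D3:**
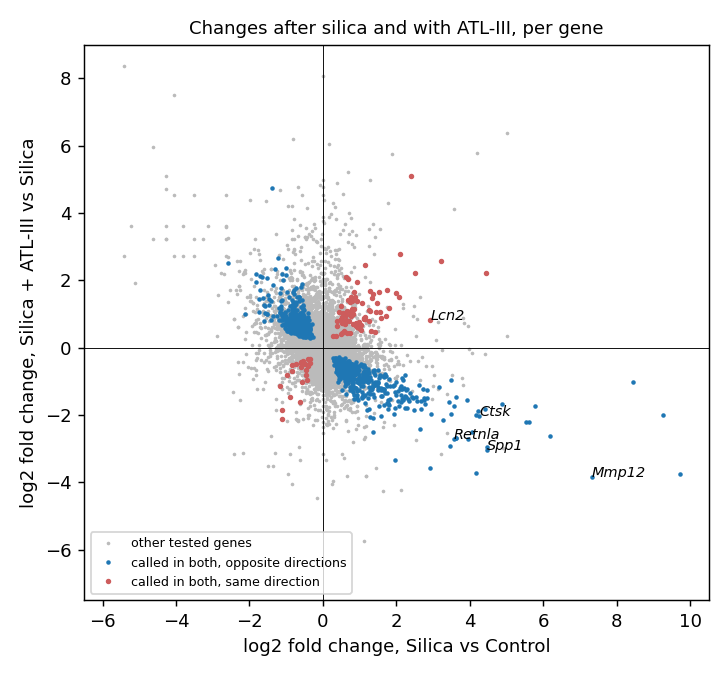
Each dot is 1 of 15459 tested genes, with the log2 fold change after silica on the horizontal axis and with ATL-III on the vertical axis. The 1000 genes called in both comparisons with opposite directions are blue and the 101 with the same direction are red, and Mmp12, Spp1, Ctsk and Retnla lie to the lower right.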

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

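Tests chosen only after the data were seen are DESeq2, its size factors in edgeR, library totals alone, and removal of the length and GC trends. The design named limma on log2(FPKM + 0.5), and not its other pseudocounts, quantile normalization or array weights. All 5 limma settings were set against edgeR once the table was seen to hold counts. Of 6682 values of named genes over 17 settings other than leaving out libraries, 6359 kept their direction and side of the threshold, 249 lost and 43 gained a call, and 31 changed sign, all of them genes that edgeR had not called. Of 188 counts, list totals and covariances over 19 such settings, 159 stayed within 1.5 times and 29 did not, as follows, and unless stated the cause was not tested. Camera with an estimated correlation called 0 lists in each comparison (8, 4 and 9 at an unadjusted p under 0.05), and fry called 14 in each. Without a filter on low values, which adds genes near 0, 1614 genes changed back and the covariance was -0.79. With an FPKM of at least 5 the covariance was -0.11. FPKM rescaled to TPM, which lowers every value where a library's FPKM sum is larger, gave 726 genes higher and 3451 lower (Silica vs Control), 2732 lower (Silica + ATL-III vs Silica), and 779 higher and 5339 lower (Silica + ATL-III vs Control). Fitting only the 6 libraries compared left 1013 genes lower for Silica + ATL-III vs Silica. The same setting raised the calls to 2866 for Silica vs Control and 2774 for Silica + ATL-III vs Control. Limma on log2(FPKM + 0.5) gave 820 genes higher for Silica vs Control, 1760 lower for Silica + ATL-III vs Control and a covariance of -0.10. At a pseudocount of 0.1 those counts were 810 and 1729, and at 1 they were 819 and 1770 with a covariance of -0.078, which was -0.094 with quantile normalization. Limma with array weights gave 2623 higher and 4937 lower (Silica vs Control), 2600 and 3228 (Silica + ATL-III vs Silica), 2643 lower (Silica + ATL-III vs Control) and 3068 genes changed back. Library totals alone gave 2021 lower for Silica vs Control and 2019 lower for Silica + ATL-III vs Control. DESeq2 called 3371, 3783 and 2889 genes in the 3 comparisons.

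With 1 library left out, genes higher ran from 528 to 2063 and lower from 293 to 1881 for Silica vs Control, from 1099 to 1930 and 826 to 1947 for Silica + ATL-III vs Silica, and from 891 to 1425 and 583 to 895 for Silica + ATL-III vs Control. Lists called ran from 20 to 22, 16 to 21 and 19 to 22, genes changed back from 310 to 1906, and the covariance from -0.30 to -0.14. Silica 2 was the library whose removal raised the silica counts, to 3944 calls, and it lay nearest to Control on the 2nd principal component (-13.2 against -53.7 and -30.6). Log2 fold changes of genes that edgeR had not called changed sign as follows. For Silica vs Control these were Map1lc3b (-0.0048 with TPM), Mtor (0.040 without the length trend) and Becn1 (0.035 without the length trend). For Silica + ATL-III vs Silica these were Sqstm1 (-0.025 with TPM, -0.010 without the GC trend). For Silica + ATL-III vs Control these were Egfr (-0.17 with TPM, -0.029 with limma, -0.039 with limma at pseudocount 0.1, -0.021 at pseudocount 1), Mtor (-0.21 with TPM, -0.031 with limma, -0.037 with limma at pseudocount 0.1, -0.025 at pseudocount 1, -0.028 with library totals), Becn1 (-0.12 with TPM), Atg5 (-0.23 with TPM, -0.041 with limma, -0.042 with limma at pseudocount 0.1, -0.040 at pseudocount 1, -0.026 with quantile normalization, -0.067 with array weights, -0.039 with library totals, -0.043 without the length trend) and Fn1 (-0.23 with TPM, -0.045 with limma, -0.046 with limma at pseudocount 0.1, -0.044 at pseudocount 1, -0.0021 with quantile normalization, -0.028 with array weights, -0.046 with library totals, -0.011 without the GC trend). With 1 library left out the sign also varied for Atg7 from -0.13 to 0.046 (Silica + ATL-III vs Silica), Sqstm1 from -0.087 to 0.32 (Silica + ATL-III vs Silica), Becn1 from -0.12 to 0.021 (Silica vs Control), Egfr from -0.0010 to 0.36 (Silica + ATL-III vs Control) and Atg5 from -0.0019 to 0.15 (Silica + ATL-III vs Control).

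The labels do not say that the sample numbers in the titles pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.13 to 0.12 (1 of 9 pairs above 0.1), and a library correlated best with its own number in 3 of 9 pairs, all between Control and Silica. A pairing between Control and Silica is therefore not excluded. With the sample number as a block edgeR called 2120, 2822 and 2109 genes, of which 2037, 2744 and 2042 were also called without it, and 841 genes changed back. Depth of 16047175 to 17792481 counts limits mainly genes with few counts, and 3 libraries per group limit changes under 2-fold.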

Other observations

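Tests chosen only after the result was seen are those on carried-over lymphoid tissue, on blood and on dilution by other cells, and the removal of the length trend, library totals alone and DESeq2's size factors were settings chosen after the data were seen. After silica clock genes were tested as a list. Of 18 clock genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone), or 2 to 4 without Control 1, Control 2, Control 3 or Silica 1. Camera called the clock list lower (adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). That call was lost without Silica 2 (adjusted p = 0.36). Cry2 fell (-0.79 ± 0.15) and Bhlhe41 rose (1.74 ± 0.24). With ATL-III 9 of 18 rose and 5 fell (9 and 5 adjusted over the list alone) with no camera call, among them the repressor Nr1d1 (-1.61 ± 0.15), Cry1 (1.23 ± 0.17) and Nfil3 (1.68 ± 0.29). The labels do not give the time of day at which lungs were taken.

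The following values compare Silica + ATL-III with Silica unless Control is named. Of 21 immediate-early and heat-shock genes, 10 rose and 1 fell (11 and 4 adjusted over the list alone). The immediate-early and heat-shock list was called higher by camera (adjusted p = 0.0048, and adjusted p = 0.61 with an estimated correlation). This camera call was lost without Silica 2 (adjusted p = 0.36). Dusp1, a phosphatase of MAP kinases, rose by 1.34 ± 0.21 and the nuclear receptor Nr4a1 by 1.64 ± 0.27. Against Control 9 of 21 rose with ATL-III, and camera called the list higher (adjusted p = 0.00056, and adjusted p = 0.48 with an estimated correlation). The call against Control was kept whichever single library was left out. Among the alveolar type 1 genes 4 of 18 fell (4 adjusted over the list alone, 2 without Silica 1), such as the water channel Aqp5 (-0.73 ± 0.14) and the junction protein Cldn18 (-0.70 ± 0.15), with no camera call. Airway secretory genes gave 4 of 21 higher and 5 lower (6 and 9 adjusted over the list alone, the lower ones 2 to 9 without Silica 1, Silica 2, Silica 3 or Silica + ATL-III 2), with the lectin Reg3g lower (-1.40 ± 0.26) and Aldh3a1 higher (0.91 ± 0.15). Igfbp6, in the mesothelial list, rose from 84.9 ± 6.53 to 284 ± 42.0 FPKM (1.76 ± 0.13).

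Of 17 B cell genes, 17 were called lower with ATL-III than in Silica (camera adjusted p = 0.41 with an estimated correlation). Lymphoid tissue carried over in the other groups stays open. The T and NK cell median fell less than that of B cells (-0.59 against -1.88, a difference of 1.28 with a 95% bootstrap interval of 1.05 to 1.56 over genes that are not independent). The T and NK cell median was -0.37 without Silica + ATL-III 2 and -0.90 without Silica + ATL-III 3. Camera had called the T and NK cell list higher after silica (adjusted p = 0.0044, and adjusted p = 0.60 with an estimated correlation), a call lost without Silica 2. Against Control the medians with ATL-III were -0.14 for T and NK cells (1 of 21 higher and 0 lower) and -1.97 for B cells. Both scores, however, were highest in Silica 2 (0.53 and 1.08) and lowest in Silica + ATL-III 2 (-0.81 and -2.11). Their deviations from the group means correlated at 0.89 over the libraries. A candidate explanation is exposure to glucocorticoids, which lower B cells in blood and raise neutrophils. Of 14 glucocorticoid-induced genes outside the fixed lists, chosen without looking at their values, 8 were called higher with ATL-III and 0 lower. The largest were Hif3a (2.65) and Rasd1 (2.09), and among those not called were Sgk1 (-0.21), Tob2 (0.14), Nfkbia (0.36) and Klf9 (0.39). The median over the 14 genes was 0.76, at percentile 100 of 10000 random lists matched on expression (camera p = 2.3e-07, and p = 0.091 with an estimated correlation). Inflammation can induce some of these glucocorticoid-induced genes, such as Cebpd (0.75), and an effect of ATL-III itself, of daily injection or of stress stays open, since no injected control is named. The time of day at which lungs were taken is not given either, and 9 of 18 clock genes rose and 5 fell with ATL-III. An effect of sampling time therefore cannot be told apart from one of the group.

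With ATL-III 18 of 22 neutrophil genes were called higher than in Silica (camera adjusted p = 0.28 with an estimated correlation). More blood left in the lungs would raise red blood cell genes, whose median over 10 genes was -0.37, below the neutrophil median by 3.33 (interval 1.80 to 4.12), although Silica + ATL-III 1 scored low for them (-1.73) and their median was -0.14 without it, -0.21 without Silica 2 and -0.82 without Silica + ATL-III 3. The interval is over genes that are not independent and leaves out the spread between libraries. Scaling between libraries is argued against by size: 4 scalings shifted the median gene by -0.12 to -0.0021, against a neutrophil median of 2.96. With shifts so small, the 17 to 18 of 22 neutrophil genes called higher under them add no further support. A higher share of neutrophils in the blood, recruitment to the lung and higher transcription per cell are not separated by these libraries and may all contribute.

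Of 34 collagen and matrix genes, 19 were called lower and 2 higher with ATL-III than in Control, or 12 lower without Control 3 (camera adjusted p = 0.35 with an estimated correlation). Dilution by other cells would lower all resident cell types alike, but the matrix median was -0.60 against -0.06 over 89 endothelial, alveolar and ciliated genes, a difference of -0.54 (interval -0.73 to -0.16). That interval is over genes that are not independent and leaves out the spread between libraries. By list the medians were -0.04 (endothelial), -0.06 (alveolar type 2), -0.05 (ciliated) and -0.26 (alveolar type 1). Camera called the alveolar type 1 list lower (adjusted p = 0.031, and adjusted p = 0.50 with an estimated correlation). That call was lost without Control 1, Control 3, Silica + ATL-III 1 or Silica + ATL-III 3. Medians of fibroblast (-0.60), smooth muscle and pericyte (-0.70) and heart and skeletal muscle genes (-1.21) were as low or lower, so a smaller share of such tissue in the samples stays open, and against Silica the alveolar type 2 median (-0.56) lay with that of matrix (-0.47). Gene length is argued against, as 18 of 34 matrix genes were lower and called with the length trend removed. Fewer matrix-producing cells or less transcription in them may underlie it, as a hypothesis that bulk tissue does not resolve.

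Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. EdgeR called 2615, 3279 and 2451 genes in the real splits and 0 in the highest other split, where at most 1317, 2054 and 695 genes had an unadjusted p under 0.05, against 5382, 5479 and 4670. The other splits mix libraries of both groups, so a group difference of any cause widens their spread and lowers their calls. Their counts are therefore no measure of the calls expected without a difference.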
